A study of Homo sapiens with 52 samples.

How the data were processed

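Open chromatin was measured by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into accessible DNA, in 52 samples of 15 groups. The cells were Kasumi-1 and HEL, lines derived from myeloid leukemias, and OCI-LY1, a line derived from a B-cell lymphoma. In the treated and control cells of the comparisons, SMARCA5, the ATPase of ISWI chromatin remodeling complexes, carried a degron tag on both alleles, per the labels. The compound dTAG-47, a bifunctional molecule that directs the tagged protein to degradation, was added at 500 nM for 2, 6 or 24 h. Controls received no dTAG-47 per the labels, while the names of the deposited tables call the controls of the synchronized cells DMSO. The series text describes the samples as biological replicates, so the p-values measure the spread between those samples. In asynchronous Kasumi-1 cells they measure only the spread within the sets of libraries described below, since the fit removes the difference between sets.

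The submitters' processing notes list Trimmomatic 0.32, Bowtie2, SAMtools, Genrich, MACS2, DiffBind, DESeq2 and deepTools, and the builds hg19, GRCh37 and dm3. The positions of the sites lie on hg19. The authors deposited 8 tables of read counts per site, of which 3 hold the same values, so that 6 distinct tables were used. Each site is a window of 400 bp or the union of windows that touch. The authors deposited raw counts per site and library, which were used here. A further 82 columns of values per library in these tables, which the authors had normalized, were not used here. The same deposited tables give the authors' log2 fold change with its standard error, a Wald score, and a p-value with its adjusted value for each site. The authors also deposited 30 lists of peaks, each with a score for the peak area and the -log10 q of each peak from the caller. Of these lists, 26 are tied by the labels to a sample or group, and the other 4 were left out. The 2 parental Kasumi-1 samples have no column in any table and were not used.

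A total of 50 libraries entered 8 comparisons, each of a treated group against its own control. Counts were tested with edgeR 4.0.16 in R 4.3.3 (TMM scaling, the default filter on low counts, robust quasi-likelihood fit, Benjamini-Hochberg adjusted p under 0.05), with DESeq2 1.42.0 as the alternative tool. In what follows, "rose" and "fell" refer to this test, and every log2 fold change is treated over control. Overlaps of sites were found with GenomicRanges 1.54.1, with at least 1 bp in common, and classes of sites were tested with camera of limma 3.58.1 at a preset correlation of 0.01 and again with an estimated correlation.

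Columns of the tables carry an arm and a letter, not a replicate number. Among the asynchronous Kasumi-1 libraries, the letters A and B stood apart from C and D: after removal of the group means, correlations of sites within a letter set were 0.562 to 0.802 and those between sets -0.741 to -0.617. The labels of these samples name a library set for 2 of the 4 replicates of each group, and the authors' deposited table was matched by a DESeq2 fit with these letters as a covariate. The letter set therefore entered the fit of the asynchronous Kasumi-1 comparisons. The labels of the synchronized samples also name library sets, but no label or column name ties the columns to them. The authors' deposited tables of these cells were matched by DESeq2 fits without a covariate. The covariate for the library set that had been planned for those fits was therefore dropped, and letter sets were run as alternatives. In G1 the letters ABC also stood apart from EF, with correlations of 0.335 to 0.707 within and -0.628 to -0.452 between sets. In size these letter sets are like 1 labelled library set against the rest of each arm, so they may be those sets. At 12 h after release AB stood apart from CD, with 0.120 to 0.240 and -0.220 to -0.140. The values at 6 h after release overlapped (-0.0388 to 0.384 and -0.336 to 0.0156). HEL and OCI-LY1 had 1 library set each.

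The library totals were 2381055 to 9161656 reads in sites for asynchronous Kasumi-1, 15641219 to 21527964 for HEL and 12847755 to 31144528 for OCI-LY1. They were 8547659 to 28886975 for G1 cells, 7140417 to 42078807 at 6 h after release and 13217854 to 27671099 at 12 h after release. The pipeline was tested on simulated data made from the mean level of each site over all libraries of a comparison, with 200 sites changed 2-fold. No difference between letter sets was simulated. Between 55.0% of the changed sites (OCI-LY1) and 95.5% (12 h after release) were recovered, with 4 to 8 false calls per comparison.

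Apart from the covariate dropped for the synchronized cells, the comparisons, the test, the threshold, the rule for named sites and most alternatives were fixed before the data were examined. The rule took, per comparison, the 6 largest rises and the 6 largest falls among sites past adjusted p 0.05 with a mean of at least 50 counts and no overlap between the normalized values of the groups. It was written for promoter sites of genes, and was applied to all sites because an annotation and a genome of this build were not used here. For the same reason, tests of CTCF motifs, of gene lists and of promoters were left out, and sites carry no gene names. The text gives the first 2 sites of each direction in full and the rest as a range. The site classes were chosen after the data were examined: sites were classed by overlap with peaks of the untreated cells of the other lines, by 4 equal groups of read count, by the width of the untreated peak (narrow under 300 bp, broad from 1000 bp, from libraries outside the comparison) and by distance under 500 kb from the start of a chromosome. Between 16 and 24 classes per comparison were adjusted together.

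Alternatives were other scaling (DESeq2 factors, total counts), DESeq2, no filter, adjusted p under 0.01, the letter sets, a block for each letter, each library left out in turn, peak lists at a stricter q of 0.001 and a reciprocal overlap of 50%. The groups of at least 3 libraries were also split in all other ways, or in 100 of them, over 10000 sites drawn at random. Libraries of HEL and OCI-LY1 are 2 per group, so a group with 1 library left out holds a lone sample that the fit assumes to vary like the other group.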

Results

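The series followed open chromatin after degradation of SMARCA5 in 3 cell lines and, for Kasumi-1, at 3 times of treatment and in synchronized cells. Asynchronous Kasumi-1 cells had 4 libraries without dTAG-47 and 4 each at 2, 6 and 24 h. HEL and OCI-LY1 cells had 2 control and 2 treated libraries each, at 6 h. Synchronized Kasumi-1 cells were treated for 6 h and held 5 libraries per arm in G1 and 4 per arm at 6 h and at 12 h after release. Asynchronous Kasumi-1 libraries held 2381055 to 9161656 reads in sites, against 7140417 to 42078807 in the other tables. Numbers of changed sites in tables of different depth are therefore not measures of the size of the response.

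The comparison of 2 h of dTAG-47 with no treatment in asynchronous Kasumi-1 cells asked which sites changed first. Mostly losses were seen: 4877 of 71772 sites fell and 1332 rose. The sites that fell had a median log2 fold change of -0.84, those that rose 0.66, and 1432 sites fell by more than 2-fold against 156 that rose as much. Sites named here and below were ordered only among those with a mean of at least 50 counts and no overlap between the groups, so sites outside this rule could change more. By this order the first fall at 2 h was chr11:189925-190325, where the normalized read count went from 194 ± 69.0 to 54.3 ± 7.13 (SD, n = 4), a log2 fold change of -1.94 (SE 0.160, adjusted p = 5.48e-12, edgeR quasi-likelihood test). Next by this rule was chr16:85454299-85454699, from 93.3 ± 28.1 to 26.2 ± 2.31 (SD, n = 4), with a log2 fold change of -1.89 (adjusted p = 5.76e-09, edgeR). The first rise by the rule was at chr8:38502369-38502769, from 37.9 ± 11.3 to 77.7 ± 25.4 (SD, n = 4; log2 fold change 0.99, SE 0.196, adjusted p = 7.21e-04, edgeR), and the second at chr7:143109105-143109505 with 0.90 (SE 0.171, adjusted p = 4.29e-04, edgeR). The next 4 falls taken by the rule ranged from -1.57 to -1.42 and the next 4 rises from 0.82 to 0.88. The authors' deposited table held 3125 falls and 774 rises. Between the letter sets, C and D alone gave 6243 changed sites and A and B alone 739; without the covariate for the letter sets edgeR called 0 sites, with 3733 at an unadjusted p under 0.05 and 112 by DESeq2. The total of 6209 was 3359 without control D, 2824 without treated library C and 2466 without treated library D. The rises moved more than the falls: they numbered 883, 828 and 697 without control B, C or D, and 389 and 269 without treated library C or D.

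After 6 h in the same cells, 9680 of 71288 sites fell and 6465 rose, with median log2 fold changes of -0.90 and 0.81. Falls of more than 2-fold were seen at 3784 sites and rises of that size at 1458. The site chr11:189925-190325 again came first of the falls taken by the rule, from 183 ± 64.8 to 27.5 ± 9.21 (SD, n = 4; log2 fold change -2.71, SE 0.216, adjusted p = 1.40e-09, edgeR), ahead of chr2:15043901-15044301, from 104 ± 52.5 to 14.9 ± 3.64 (SD, n = 4; -2.60, adjusted p = 2.31e-08). The first rise by the rule was at chr4:57965036-57965436, from 34.1 ± 13.4 to 107 ± 18.1 (SD, n = 4; 1.68, adjusted p = 9.97e-07, edgeR), and the second at chr6:131576599-131576999, from 38.8 ± 14.8 to 100.3 ± 22.6 (SD, n = 4; 1.37, adjusted p = 1.80e-05). Of the next 4 rises taken by the rule, 1.20 to 1.25 in size, chr4:54672279-54672679 and chr4:56259672-56260072 lay in the same part of chromosome 4 as the first. The authors' deposited table held 10749 falls and 8061 rises. Scaling to total counts changed the balance to 8178 falls and 8242 rises. Letters A and B alone gave 4841 changed sites and C and D alone 6099; without the covariate edgeR called 0, with 8637 at an unadjusted p under 0.05 and 3197 by DESeq2, and without control D the total of 16145 was 9428. The number of rises was less stable than that of falls: 4150, 3903 and 3650 sites rose without control A, B or D (8449, 8377 and 5778 fell), and letters C and D alone gave 4669 falls and 1430 rises.

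At 24 h the response in Kasumi-1 covered 16917 falling and 13797 rising sites of 71837, with 7964 falls and 3101 rises of more than 2-fold. The count at chr11:189925-190325 went from 197 ± 69.7 to 20.9 ± 6.32 (SD, n = 4; log2 fold change -3.37, SE 0.193, adjusted p = 6.22e-18, edgeR) and that at chr21:27173818-27174218 from 115 ± 36.6 to 12.6 ± 5.75 (SD, n = 4; -3.28, adjusted p = 1.18e-14). The first rise by the rule, at chr17:48876138-48876538, was from 20.7 ± 17.7 to 96.7 ± 53.0 (SD, n = 4; 2.15, SE 0.210, adjusted p = 4.56e-11, edgeR); both letter sets rose there from different levels, and without the set covariate the adjusted p was 0.0871. The site chr4:57965036-57965436 followed with 1.84 (SE 0.187, adjusted p = 1.29e-10, edgeR). Scaling to total counts turned the balance to 15355 falls and 16763 rises, as did leaving out control B (15123 falls, 16056 rises) or treated library B (15645 falls, 16635 rises). Sites called by the authors' deposited table were 15392 falls and 13719 rises. Letters A and B alone gave 9581 changed sites and C and D alone 30597; without the covariate edgeR called 1814, with 15364 at an unadjusted p under 0.05 and 9931 by DESeq2.

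Because the 3 times shared their control libraries, the times were also compared directly. Sites that fell at 2 h were lower still at the later times: their median log2 fold change was -0.84 at 2 h, -0.99 at 6 h and -1.39 at 24 h, and 84.0% of those tested were also called as falls at 6 h and 96.8% at 24 h. Of the sites that rose at 2 h, 58.7% also rose at 6 h and 80.2% at 24 h. Common controls can raise such shares, and few rises were shared with divided controls (below). The edgeR contrast of 24 h against 2 h called 4538 sites lower and 3924 higher of 72039; 6 h against 2 h called 864 lower and 488 higher, and 24 h against 6 h only 96 lower and 44 higher. At chr11:189925-190325 the count was 187 ± 66.3 without treatment, 52.3 ± 7.05 at 2 h, 28.1 ± 9.43 at 6 h and 19.8 ± 6.00 at 24 h (SD, n = 4). The site chr8:38502369-38502769 rose over the same times from 36.4 ± 10.9 to 75.0 ± 24.9, 83.2 ± 21.7 and 127 ± 33.8 (SD, n = 4). Over 10000 sites, 564 fell at both 2 and 6 h where independent calls would give 89.2, and with the controls divided between the times 138 fell at both against 16.3. The log2 fold changes of these times had a correlation of 0.798, against 0.475 in simulated unchanged groups with common controls. For rises, the divided controls left 4 shared sites at 2 and 6 h, close to the 2.42 of independent calls, and 3 sites were called in opposite directions. They left 18 shared rises at 2 and 24 h (8.89 if independent) and 136 at 6 and 24 h (30.7 if independent). Total-count scaling gave 534 lower and 545 higher at 6 h against 2 h. These contrasts depended on single libraries. The 24 h against 2 h contrast called 5184 and 3869 sites without library C or D of 24 h, and 4819 and 5561 without C or D of 2 h. The near balance of its directions was not stable: sites higher at 24 h numbered 2147, 2560, 1824 and 1442 without A, B, C or D of 24 h, against 4569, 5253, 3360 and 2427 lower. Without C or D of 2 h, 1549 and 1756 were higher and 3270 and 3805 lower. The contrast of 6 h against 2 h called 242, 391 and 3739 without A, C or D of 6 h, and 623, 490, 275 and 426 without A, B, C or D of 2 h. That of 24 h against 6 h called 7 and 639 without A or D of 6 h, and 2 and 8 without C or D of 24 h.

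**Figure D1:**
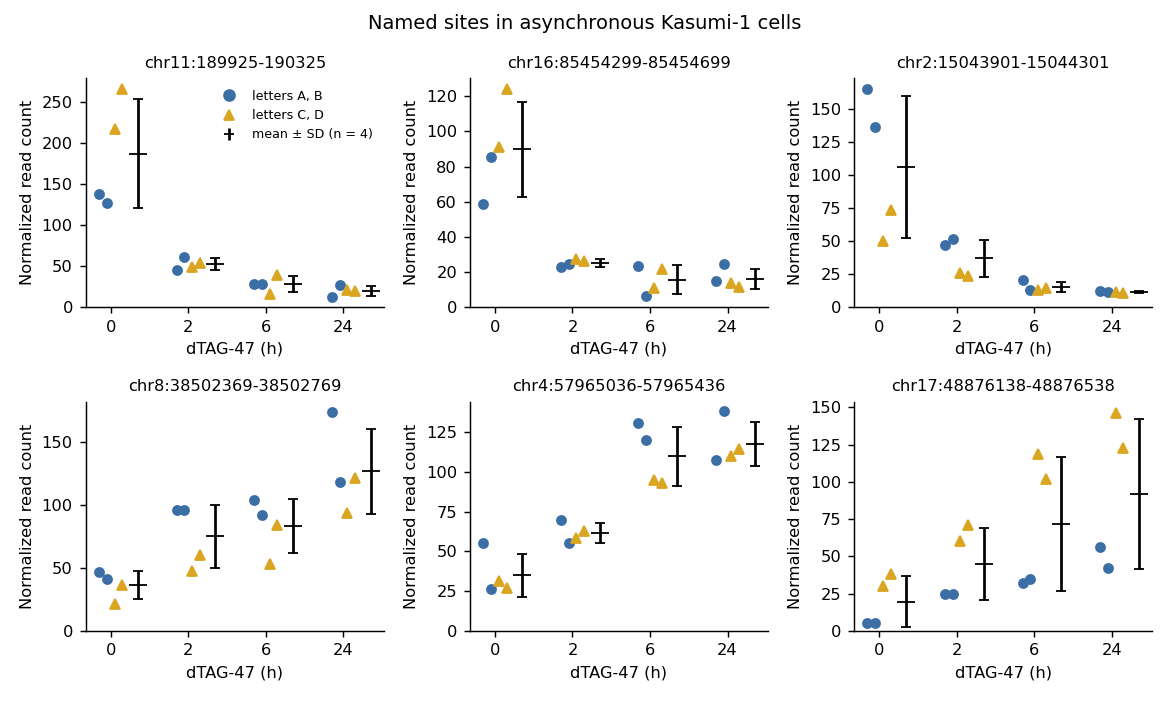
Normalized read count (vertical axes) at 6 named sites in asynchronous Kasumi-1 cells against hours of dTAG-47 (0, 2, 6 and 24 h); points are libraries, with shapes for the letter sets, and black bars the mean ± SD of 4 libraries. The upper sites were lower and the lower sites higher at each time of treatment than at 0 h in mean count, as at chr11:189925-190325 with 187 at 0 h and 19.8 at 24 h.

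In HEL cells, treated for 6 h to ask whether the response held in another myeloid line, gains and losses were nearly equal in number: 13320 of 72176 sites rose and 12143 fell. Median log2 fold changes were 0.68 and -0.54, and 2383 sites rose and 1152 fell by more than 2-fold. The first rises by the rule were at chr9:26813270-26813670, from 16.3 ± 1.62 to 92.1 ± 5.18 (SD, n = 2; log2 fold change 2.48, SE 0.272, adjusted p = 4.04e-13, edgeR), and at chr9:20786229-20786629, from 15.4 ± 0.327 to 85.5 ± 9.46 (SD, n = 2; 2.46, adjusted p = 2.56e-12). The site chr14:107238841-107239241 fell from 96.7 ± 0.548 to 17.5 ± 3.18 (SD, n = 2; -2.46, SE 0.263, adjusted p = 1.21e-13, edgeR) and chr20:49545887-49546287 from 163 ± 12.3 to 32.2 ± 6.97 (SD, n = 2; -2.33, adjusted p = 6.13e-18). The next 4 sites of each direction ranged from 2.38 to 2.41 and from -2.10 to -2.08. The authors' deposited table, which a DESeq2 fit matched, held 4731 rises and 5005 falls. Scaling to total counts gave 15264 rises and 10149 falls, and without control B the total of 25463 was 16939.

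OCI-LY1 cells extended the question to a B-cell line, and 10548 of 59316 sites fell and 10615 rose at 6 h. Losses were the deeper changes here, with a median of -1.04 against 0.85 and 5640 falls of more than 2-fold against 3539 rises. A pair of sites on chromosome 16 lost nearly all of their reads: chr16:31967552-31967952 went from 214 ± 22.8 to 3.56 ± 0.292 (SD, n = 2; log2 fold change -5.84, SE 0.300, adjusted p = 0.00199, edgeR) and chr16:32993642-32994042 from 102 ± 18.3 to 1.78 ± 0.146 (SD, n = 2; -5.72, adjusted p = 0.00322). Further falls taken by the rule, at chr6:148434-148834, chr16:33763954-33764354, chr15:22460977-22461377 and chr14:106873436-106873836, ranged from -4.99 to -4.62, and whether reads map uniquely at these sites could not be checked. The rises taken first by the rule were chr7:64253780-64254180, from 16.0 ± 8.39 to 114 ± 6.83 (SD, n = 2; 2.87, SE 0.331, adjusted p = 0.00387, edgeR), and chr7:86850686-86851086, from 20.9 ± 6.59 to 133 ± 27.3 (SD, n = 2; 2.62, adjusted p = 0.00376). Falls in the authors' deposited table numbered 9032 and rises 6258. The balance depended on the scaling: total counts gave 9223 falls and 11569 rises, and DESeq2 factors 11227 falls and 9645 rises. The treated libraries differed from each other more than the controls did, with a chi-square over sites per degree of freedom of 10.6 against 2.10. Treated library B held 12847755 reads in sites against 25024238 in A. Every library moved the total of 21163: it was 8106 without control A, 6154 without control B, 36657 without treated library A and 32212 without treated library B. Without control A or B the falls outnumbered the rises, by 5049 to 3057 and 3993 to 2161.

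G1 cells were examined to separate the response from the cell cycle. Of 101607 sites, 15365 fell and 13404 rose, and large falls outnumbered large rises by 7689 to 3537. The site chr6:148444-148844 fell from 420.4 ± 132 to 15.1 ± 4.81 (SD, n = 5; log2 fold change -4.77, SE 0.266, adjusted p = 3.44e-06, edgeR) and chr11:189931-190331, which overlaps the first of the falls named in asynchronous cells, from 987 ± 189 to 61.1 ± 7.09 (SD, n = 5; -4.01, adjusted p = 1.09e-07). Named rises began with chr16:69873132-69873532, from 15.0 ± 5.62 to 85.1 ± 29.5 (SD, n = 5; 2.44, SE 0.317, adjusted p = 1.86e-04, edgeR), and chr22:41915800-41916200, from 24.3 ± 7.07 to 114 ± 55.2 (SD, n = 5; 2.24, adjusted p = 4.09e-04). The next 4 falls ranged from -3.72 to -3.32 and the next 4 rises from 1.89 to 1.96. The authors' deposited table held 17772 falls and 13130 rises. Scaling to total counts turned the balance to 13871 falls and 16338 rises. With a covariate for the letter sets ABC and EF the total of 28769 became 54565, of which 25228 fell and 29337 rose, and with a block for each letter 56476 (26010 falls, 30466 rises); letters A, B and C alone gave 35075 and E and F alone 37562.

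At 6 h after release, 22950 of 89343 sites fell and 21659 rose, with medians of -0.75 and 0.63. By the rule the falls began with chr19:56820933-56821333, from 198 ± 68.9 to 15.5 ± 5.65 (SD, n = 4; log2 fold change -3.66, SE 0.306, adjusted p = 1.48e-06, edgeR), and chr14:107238853-107239253, from 82.0 ± 27.7 to 6.89 ± 2.88 (SD, n = 4; -3.56, adjusted p = 1.99e-07). The latter overlaps the first of the falls named in HEL. The rises began with chr22:41915806-41916206, from 17.1 ± 6.93 to 92.1 ± 22.5 (SD, n = 4; 2.43, SE 0.251, adjusted p = 1.49e-06, edgeR), and chr22:37686856-37687256, from 19.2 ± 2.36 to 98.0 ± 8.98 (SD, n = 4; 2.32, adjusted p = 9.12e-08). Falls in the authors' deposited table numbered 22415 and rises 19502. Scaling to total counts turned the balance to 19224 falls and 27567 rises, and letters C and D alone gave 20173 changed sites against 37684 for A and B.

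At 12 h after release the numbers were 27239 falls and 25660 rises of 91273 sites, with 10907 falls of more than 2-fold against 3255 rises. The site chr10:127210640-127211040 went from 158 ± 13.6 to 7.88 ± 4.58 (SD, n = 4; log2 fold change -4.33, SE 0.211, adjusted p = 1.85e-15, edgeR) and chr6:148443-148843 from 338 ± 28.0 to 17.2 ± 3.48 (SD, n = 4; -4.33, adjusted p = 7.64e-19). The first rises by the rule were at chr9:35705958-35706358, from 17.1 ± 4.49 to 89.9 ± 13.5 (SD, n = 4; 2.32, SE 0.193, adjusted p = 6.38e-11, edgeR), and at chr2:48340362-48340762, from 26.2 ± 10.7 to 131 ± 14.7 (SD, n = 4; 2.29, adjusted p = 3.85e-11). The authors' deposited table held 25080 falls and 22270 rises. Scaling to total counts turned the balance to 24512 falls and 30623 rises. Letters A and B alone gave 51226 changed sites and C and D alone 39338.

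**Figure D2:**
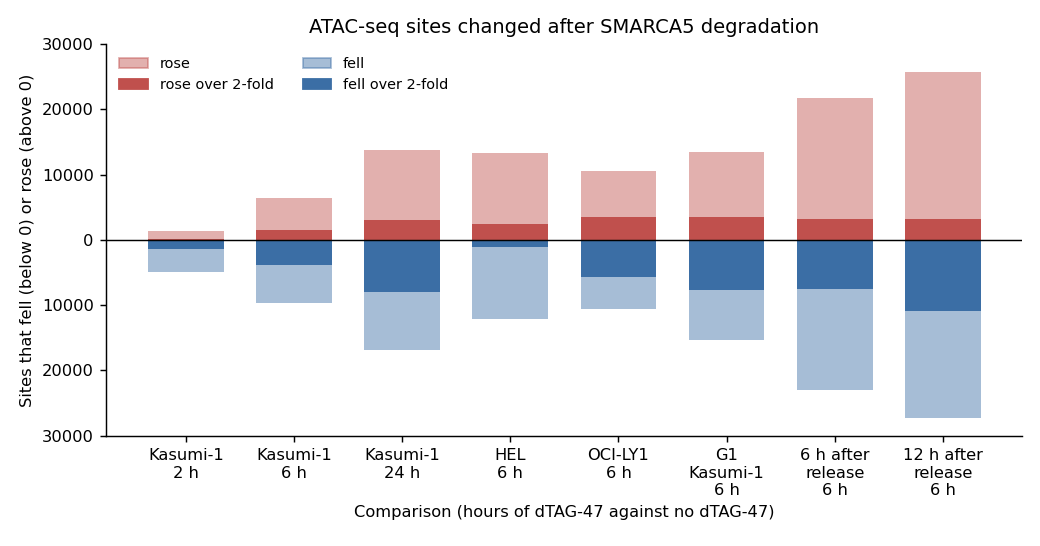
Number of sites that rose (above 0) or fell (below 0) in each of the 8 comparisons, with the part that changed more than 2-fold in the darker shade. At 2 h in Kasumi-1 the falls numbered 4877 and the rises 1332, and in HEL 13320 sites rose and 12143 fell.

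Changed sites were shared between the lines more than independent calls would give, in both directions. At 6 h, 3365 sites fell in both Kasumi-1 and HEL where 1569 would be shared if calls were independent, 4457 in Kasumi-1 and OCI-LY1 (1853 if independent) and 3837 in HEL and OCI-LY1 (2071 if independent). The shared rises of these pairs numbered 703 (172 if independent), 436 (66.3) and 688 (145). Of 19116 sites tested in all 3 lines, 2204 fell in each (502 if independent) and 88 rose in each (1.12 if independent). Opposite calls were seen at 83 sites between Kasumi-1 and HEL, 9 between Kasumi-1 and OCI-LY1 and 115 between HEL and OCI-LY1. In G1 cells 7171 of the sites that fell in asynchronous Kasumi-1 cells at 6 h fell too, with 7922 at 6 h and 8740 at 12 h after release. Across all 8 comparisons 18553 sites were tested, of which 1099 fell in every one and 7 rose in every one. Only sites present in the tables of all 3 lines could be counted here, and sites open in the other lines fell more often than they rose (below). The excess of falls is thus partly set by which sites could be counted. The comparisons are also not independent, since most are of Kasumi-1 and the times in asynchronous cells shared controls. The median log2 fold changes over the 8 comparisons were -3.04 at chr11:189925-190325, -2.95 at chr4:2443367-2443767 and -2.90 at chr15:70805097-70805497, and among the rises 1.11 at chr13:86382960-86383360 and 0.91 at chr12:92424363-92424763. Whether the size of the response differed between lines was not tested, since each table was scaled on its own.

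Whether a site was open in the other lines went with its direction of change. Sites open in the untreated cells of the other 2 lines fell far more often than they rose, while sites not open in the other 2 lines rose more often than they fell, except at 2 h in Kasumi-1. In Kasumi-1 at 6 h, 26.2% of the 21395 sites open in the other 2 lines fell and 1.56% rose, against 5.22% and 14.6% of the 32612 sites not open in the other lines. At 2 h the sites open in the other 2 lines already fell in 11.7% of cases against 3.19%, with 2.47% of the sites not open elsewhere rising. By 24 h the falls were 44.8% against 10.6% and the rises 4.88% against 28.4%. HEL showed 34.9% falls against 7.93% and OCI-LY1 29.2% against 9.24%; rises were 5.28% against 25.8% and 4.09% against 27.3%. In G1 cells falls were 31.3% against 7.32%, at 6 h after release 49.5% against 13.5% and at 12 h after release 53.1% against 17.8%. Among the sites open in the other 2 lines, the narrow class of untreated peak width fell most often of the widths: 19.8% at 2 h, 38.5% at 6 h and 60.9% at 24 h in asynchronous cells, 51.8% in G1, 65.4% at 6 h and 73.5% at 12 h after release. Width was not separated from read count. Sites of this class in the lowest of 4 groups of read count fell at 17.5%, 33.7% and 61.6% at 2, 6 and 24 h. The shares there were 51.7% in G1, 64.0% at 6 h and 66.0% at 12 h after release. The camera test sets a class against all other sites, so a call is relative. At 2 h it is no test of a rise of sites not open in the other 2 lines, which fell more often than they rose. For sites open in the other 2 lines, camera at the preset correlation gave adjusted p = 2.03e-20 in Kasumi-1 at 6 h and 1.46e-07 at 2 h. With an estimated correlation the calls held at 6 h (adjusted p = 0.0138) and at 12 h after release (adjusted p = 0.0320). They were lost at 2 h (adjusted p = 0.0585 with an estimated correlation), 24 h (0.0974), in HEL (0.0738), OCI-LY1 (0.182), G1 (0.274) and at 6 h after release (0.0656). For sites not open in the other 2 lines, they held at 2 h (adjusted p = 0.0254), 6 h (0.0116), 24 h (0.00154) and 12 h after release (9.34e-04), and were lost in HEL (adjusted p = 0.0738 with an estimated correlation), OCI-LY1 (0.172), G1 (0.101) and at 6 h after release (0.0656). The synchronized values come from fits without letter sets. With these sets as a covariate and an estimated correlation, the sites open in the other 2 lines had adjusted p = 0.00177 in G1, 0.103 at 6 h and 0.0585 at 12 h after release, and those not open there 0.00177, 0.103 and 0.00669 (camera). The classes were chosen after the data were examined, as was the limit to sites with an untreated Kasumi-1 peak in libraries outside the comparison. Under that limit the sites not open in the other 2 lines rose and fell in 2.70% and 2.63% of cases at 2 h, 11.3% and 4.93% at 6 h, 26.3% and 9.31% at 24 h, 10.8% and 7.13% in G1, 26.1% and 12.0% at 6 h and 34.7% and 15.0% at 12 h after release. Those under a narrow peak fell more often than they rose at 2 h (4.31% against 2.19%) and in G1 (11.3% against 9.90%). With a covariate for the letter sets in G1, 55.9% of the sites open in the other 2 lines fell and 39.7% of those not open there rose; with a block for each letter these were 57.8% and 41.2%. These shares moved with the number of calls: at 2 h, letters A and B alone gave falls at 1.21% of the sites open in the other 2 lines. With 1 library left out, the share that fell of sites open in the other 2 lines moved by more than 1.5 times in 8 cases and not in 50. The share that rose of sites not open there moved in 12 cases and not in 46. Under other settings the former moved in 18 cases and not in 60, and the latter in 21 and not in 57.

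**Figure D3:**
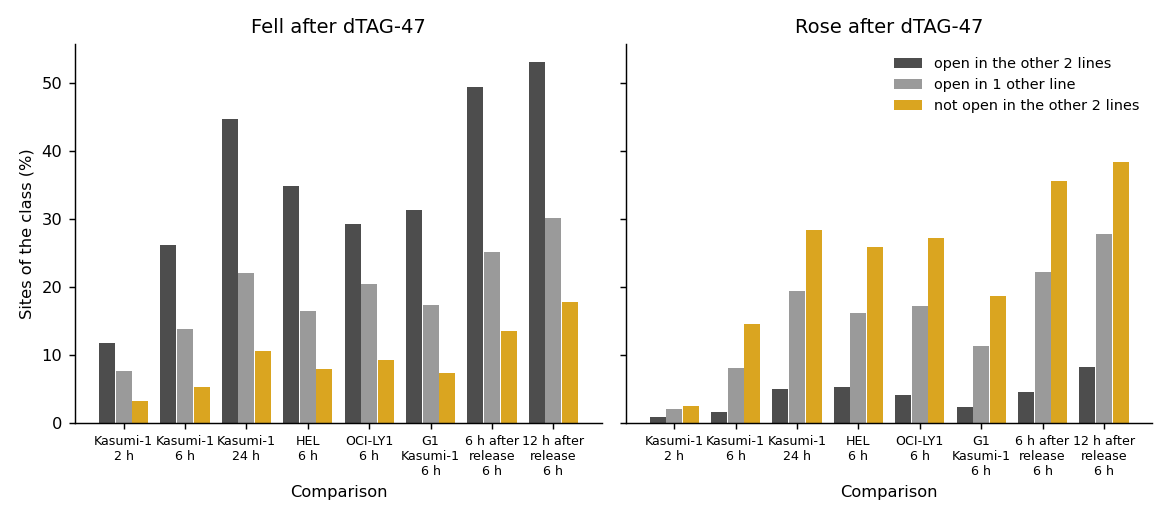
Percent of sites that fell (left) or rose (right) in each comparison, by whether the site was open in untreated cells of the other 2 lines, of 1 of them or of neither. At 12 h after release 53.1% of the sites open in the other 2 lines fell and 38.4% of the sites not open in the other 2 lines rose.

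The share of changed sites also differed along the genome. Chromosome 19 had the largest share of falling sites of any chromosome in 7 of the 8 comparisons, with 18.2% in Kasumi-1 at 6 h, 31.9% in HEL, 29.9% in OCI-LY1 and 42.4% at 12 h after release. On chromosome 4, the part from 52 to 60 Mb was dense with sites in Kasumi-1, with 208 of every 10000 tested sites in asynchronous cells at 6 h and 70.0 to 83.7 in synchronized cells, against 19.8 in HEL and 10.6 in OCI-LY1. Of the 1481 sites there, 39.9% rose in Kasumi-1 at 6 h with a median log2 fold change of 0.55, against 12.4% of sites on the rest of the chromosome. At 2 h 1.76% rose, against 2.53% on the rest of the chromosome, and at 24 h 29.9% against 24.0%. Of the Kasumi-1-only sites elsewhere, 2.51% rose at 2 h, 13.4% at 6 h, 28.3% at 24 h, 18.6% in G1, 35.3% at 6 h and 38.1% at 12 h after release. In synchronized cells treated for 6 h, 26.3% rose in G1 (16.2% on the rest), 53.7% at 6 h (26.7%) and 56.8% at 12 h after release (30.1%), while 14.0% rose in HEL (20.5%) and 6.35% in OCI-LY1 (19.4%). Letter sets differed: the median log2 fold change of the part was 0.74 in A and B and 0.40 in C and D at 6 h, 0.73 and 0.12 at 24 h and 0.23 and -0.05 at 2 h.

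**Figure D4:**
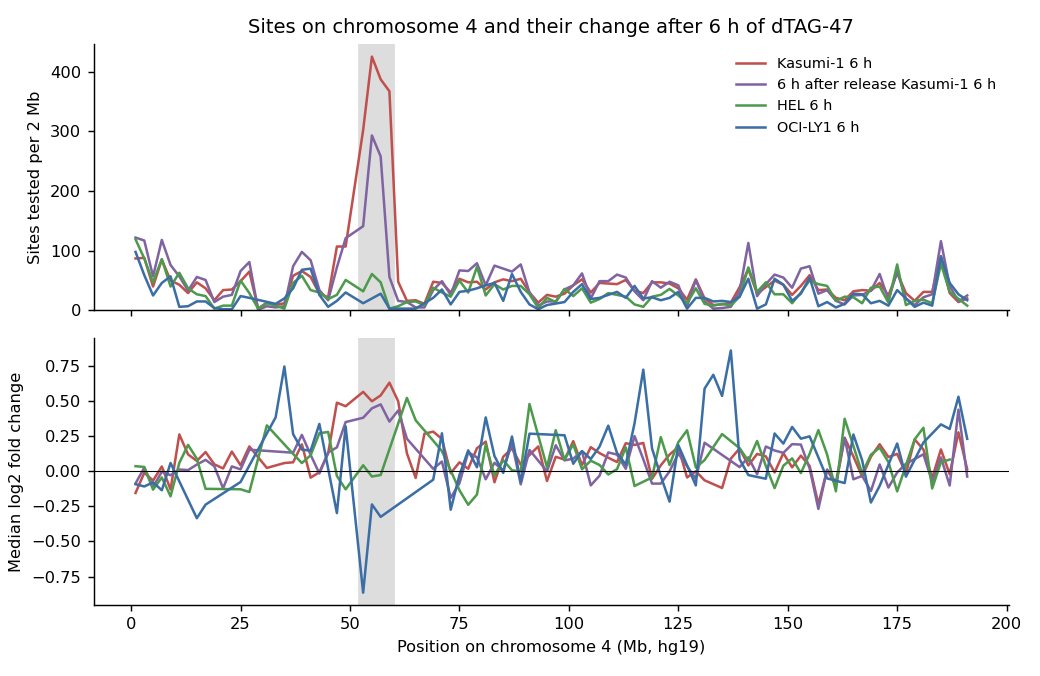
Sites tested per 2 Mb (upper) and their median log2 fold change after 6 h of dTAG-47 (lower) along chromosome 4 in Mb on hg19; each line is 1 comparison and the grey band marks 52 to 60 Mb. In the band the median log2 fold change was 0.55 in asynchronous Kasumi-1 cells, 0.44 at 6 h after release, -0.01 in HEL and -0.37 in OCI-LY1.

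The authors' deposited lists of peaks, called on pooled libraries and described here without a test, gave 48896 peaks for untreated asynchronous Kasumi-1 cells and 53242, 38187 and 54966 at 2, 6 and 24 h. Each of these lists pools only 2 of the 4 libraries of its group. The depth of the pooled libraries was not taken into account, so differences between lists are not measures of a change in chromatin. Median widths were 417 bp without treatment and 367, 479 and 365 bp at these times. In HEL the number went from 64965 to 68298 with a width of 605 and 551 bp, and in OCI-LY1 from 55821 to 50031 with 553 and 555 bp. A treated peak overlapped 90.5% of the untreated Kasumi-1 peaks at 2 h, 71.4% at 6 h and 82.6% at 24 h, with 88.2% in HEL and 75.0% in OCI-LY1. Of the 9 pairs of lists, treated peaks had the smaller median width in 7.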

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

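All tests of explanations in this part were chosen after the results were seen. Libraries far from the rest of their group were sought in 78 groups of values, of which 5 held one, and chance gives about 1 in 20.

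Of the sites between 52 and 60 Mb of chromosome 4, 39.9% rose in asynchronous Kasumi-1 cells at 6 h, but only 1.76% at 2 h. The median log2 fold change of all sites in this part was 0.55 at 6 h. More copies of this part in the treated cultures were not excluded: the part lay above Kasumi-1-only sites elsewhere in 7 of the 8 letter sets at 6 h, and DNA copies were not analysed here. A larger share of background reads in the treated libraries was not excluded either, since among the weakest sites the part rose by only 0.10 (log2) more than Kasumi-1-only sites elsewhere in G1, though by 0.42 in asynchronous cells at 6 h and by 0.41 and 0.48 at 6 and 12 h after release. These explanations cannot be told apart from an effect of treatment, which was not tested. In HEL the median of the part was -0.01 and in OCI-LY1 -0.37.

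Sites open in the other 2 lines fell more often than sites not open there. Their level of read counts as the whole cause is argued against by the difference within groups of like read count, which was at least 6.14 percentage points over 4 such groups and 8 comparisons. A larger share of background reads in the treated libraries would lower strong sites and raise weak ones. In the group with the highest read counts the medians of the classes differed by at least 0.16 (log2) in each of the 8 comparisons. Levels were not matched within that group, so this difference does not decide. In the lowest group the sites open in the other 2 lines had medians of -0.98 to -0.33. In HEL as a whole, the lowest group rose and the highest fell more often (below), so background was not excluded. The GC content of the sites may still account for part of the difference and could not be tested without the genome. An effect of treatment that depends on what binds the shared sites is a hypothesis that was not tested.

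At chr2:15043901-15044301 after 6 h of dTAG-47, library A had a normalized count of 20.3, while the other 3 lay between 12.7 and 13.8. In treated G1 cells at chr11:189931-190331, library A had 73.4 and the others 55.7 to 60.5. In the control of 6 h after release at chr22:41915806-41916206, library B had 27.4 and the others 12.5 to 14.3. Treated library A at 12 h after release held 27671099 reads in sites, against 14014605 to 14655299 in the others. Treated library D of that group had 11.1% of its reads in the top 1% of sites, against 11.6% to 11.7%.

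Several named sites differed between times of treatment in asynchronous Kasumi-1 cells by edgeR's quasi-likelihood test with BH adjustment, with n = 4 per time. These sites were chosen for large changes in the same libraries, which can inflate differences between times. From 6 to 24 h no named site differed (lowest adjusted p = 0.0973, edgeR). From 2 to 6 h the log2 change was 0.80 at chr4:57965036-57965436 (adjusted p = 0.00998, edgeR), -1.12 at chr2:15043901-15044301 (adjusted p = 0.0228) and 0.69 at chr17:48876138-48876538 (adjusted p = 0.0473). From 2 to 24 h it was 0.87 at chr8:38502369-38502769 (adjusted p = 7.07e-04, edgeR), 0.75 at chr7:143109105-143109505 (adjusted p = 9.83e-04) and 0.96 at chr4:57965036-57965436 (adjusted p = 1.30e-04). The same contrast gave 1.09 at chr17:48876138-48876538 (adjusted p = 1.11e-04, edgeR) and -1.36 at chr11:189925-190325 (adjusted p = 1.76e-04). It also gave -1.39 at chr2:15043901-15044301 (adjusted p = 8.17e-04, edgeR) and -1.68 at chr21:27173818-27174218 (adjusted p = 1.33e-04).

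Other splits of the libraries were tried over 10000 sites drawn at random. In asynchronous Kasumi-1 cells the treated and control libraries gave 765 changed sites at 2 h, 2216 at 6 h and 4360 at 24 h. The highest of the other splits among 34 gave 0 each time (1 split as large, the real one). The fit there held the letter set as a covariate, so only splits that kept the letter sets even are like the real one. Such splits are too few to exclude chance. In synchronized cells, fitted without a covariate, the real split at 6 h after release gave 5005 against 0 for the highest of the others among 35 splits. At 12 h after release it gave 5855 against 16, from the split of letters AB against CD. The labels name library sets at both times after release. Splits even over such sets are again too few to exclude chance there. In G1 cells the real split gave 2941 and the highest of the others among 100 gave 1810, so chance can be excluded. The split of letters ABC against EF, of 6 and 4 libraries, gave 2735, nearly as many. This points to a structure of the samples, which may be the labelled library sets. With these letter sets as a covariate 54565 of all sites tested were called. The differences between times were fitted with the letter sets as well, so the same limit applies and chance was not excluded. For 6 h against 2 h the real split gave 208 against 14 among 35 splits, and for 24 h against 2 h 1115 against 13. For 24 h against 6 h the real split gave 17 sites and another gave 61, so that 2 of the 35 splits were as large.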

How the results depend on the processing

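The tests with letter sets in synchronized cells, with a block for each letter, without the chromosome 4 part, at sites with an untreated Kasumi-1 peak and with an estimated correlation were chosen after the data were seen; the other alternatives were planned. The columns carry letters and no replicate numbers, so the letter shared by the arms served as the replicate block. With it 56476 sites changed in G1, and no other total of changed sites or contrast of times moved by more than 1.5 times; HEL and OCI-LY1 had 2 pairs each. No named site reversed, but these sites were chosen for a lack of overlap between the groups. Leaving out 1 library could therefore hardly reverse them, and this is no test of the response. With 1 library left out 232 site values kept direction, and under other settings 222 kept direction and call. A further 10 kept direction but lost the call. Of these, 9 were without the set covariate (adjusted p = 0.0871 to 0.871, edgeR) and 1 in letters A and B alone, chr7:143109105-143109505 at 2 h (adjusted p = 0.274). Without the set covariate edgeR called 0 sites at 2 h (3733 at an unadjusted p under 0.05, 112 by DESeq2), 0 at 6 h (8637 and 3197) and 1814 at 24 h (15364 and 9931). Letter sets add spread within groups, which the covariate removes. Letters A and B alone gave 739, 4841 and 9581 changed sites at 2, 6 and 24 h, and letters C and D alone 6243, 6099 and 30597; the cause was not tested. In synchronized cells a covariate for the letter sets gave 54565 changed sites in G1, and letters C and D alone 20173 at 6 h after release; the cause was not tested. With DESeq2 the changed sites numbered 2838 in Kasumi-1 at 2 h, 9736 in HEL and 270 for 24 h against 6 h; the cause was not tested. At adjusted p under 0.01 they were 2356 and 7245 in Kasumi-1 at 2 and 6 h, 16324 in HEL, 7389 in OCI-LY1 and 14477 in G1, by construction fewer.

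At the same stricter threshold, by construction, fewer sites fell in both comparisons of a pair: 1755 at 2 and 6 h, 2102 at 2 and 24 h and 5027 at 6 and 24 h in Kasumi-1. For Kasumi-1 at 6 h the shared falls were 1670 with HEL, 1700 with OCI-LY1, 3613 with G1, 4359 with 6 h and 4883 with 12 h after release. HEL and OCI-LY1 shared 1742, and G1 shared 8033 with 6 h and 8965 with 12 h after release. Shared rises were 99 at 2 and 6 h, 177 at 2 and 24 h and 1630 at 6 and 24 h. For Kasumi-1 at 6 h they were 219 with HEL, 61 with OCI-LY1, 743 with G1, 1116 with 6 h and 1362 with 12 h after release. HEL and OCI-LY1 shared 155 rises, G1 shared 3425 and 3639 with 6 and 12 h after release, and the latter pair shared 9985.

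Leaving out 1 library at a time gave 2466 to 5669 changed sites at 2 h (3359 without control D, 2824 without treated C, 2466 without treated D), 9428 to 15999 at 6 h (lowest without control D) and 22321 to 32280 at 24 h in Kasumi-1. The ranges were 16939 to 20581 in HEL (lowest without control B), 6154 to 36657 in OCI-LY1, 20938 to 30058 in G1, 38739 to 46603 at 6 h and 48230 to 52400 at 12 h after release. OCI-LY1 gave 8106 without control A, 6154 without control B, 36657 without treated A and 32212 without treated B; the cause was not tested. Contrasts of times gave 242 to 3739 for 6 h against 2 h, 3869 to 9858 for 24 h against 2 h and 2 to 639 for 24 h against 6 h. The number and overlap of peaks moved by less than 1.5 times under each alternative run. The smallest library, with 2381055 reads in sites, was of asynchronous Kasumi-1 cells. Tests of CTCF motifs and of gene lists were not run, for lack of a genome and annotation of this build.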

Other observations

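The classes below were chosen after the data were examined. Sites within 500 kb of the start of a chromosome were not called by camera of limma in any of the 8 comparisons (adjusted p = 0.386 in OCI-LY1 and 0.821 at 12 h after release). Of the 331 such sites in OCI-LY1, 21.8% rose and 15.4% fell, and of the 357 at 12 h after release 30.0% rose and 30.0% fell. Of the broad peaks open in the other 2 lines, 5.82% fell in Kasumi-1 at 2 h and 17.7% at 6 h, against 19.8% and 38.5% of the narrow ones. The difference between widths was not tested.

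Of the 18044 sites in the lowest of 4 equal groups of read count in HEL, 24.3% rose and 13.4% fell, while in the highest group 12.2% rose and 26.2% fell. In Kasumi-1 at 6 h the lowest group rose at 10.1% and fell at 13.8% of sites, and the highest rose at 5.38% and fell at 15.0%. The 7 sites that rose in all 8 comparisons included chr22:31627312-31627712, chr7:12677913-12678313, chr20:3137993-3138393, chr17:39944677-39945077 and chr5:94129094-94129494. Their median log2 fold changes over the comparisons were 0.86, 0.85, 0.71, 0.71 and 0.48. Recurrent falls included chr3:123361171-123361571 with -2.88, chr15:79888354-79888754 with -2.75 and chr16:27878875-27879275 with -2.74. The authors' deposited peak lists of single libraries of synchronized cells, 10 in number, held 23379 to 37812 peaks.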
